A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

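RNA of 4 knockout cultures was compared with a reference RNA on 8 two-colour arrays. Per the labels, one channel of each array held the knockout RNA and the other the reference, in Alexa 532 and Alexa 647, with 4 arrays in each orientation. The series' design text states that the samples were run in duplicate with exchanged dyes, so the 2 arrays of a condition were taken as 1 RNA sample, and n counts cultures. Nothing in the labels gives more than 1 culture per condition.

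Per the file headers, the deposited scanner files hold the mean and median spot intensity and the median background intensity of each spot for both dyes, each in 2 scans of different gain, with no normalization; the mean spot intensity was used, and the median only to find saturated spots. The software that quantified the spots is not given in the sources used here. The authors' deposited value table holds 1 value per spot and array on a log10 scale. Set against the scanner files, these values behaved as the log10 of Alexa 532 over Alexa 647 without exchange of sign for the swapped dyes: their correlation with that ratio was 0.714 to 0.912 on the 8 arrays, with slopes of 0.655 to 1.04. That held when spots were put in raster order over the slide; in the scanner's own numbering the correlation was 0.0248 to 0.356. The medians of the deposited columns lay between -0.03 and 0.06, so their centring step stays unknown. The probe annotation was joined to the deposited values by their shared spot number, so every gene name rests on the raster order found for those values, which no other source gave. It gave 1 symbol to 133 probe positions, several to 0 and none to 2555; symbols are those of the platform annotation.

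The high-gain scan was used for the main values, because the low-gain background of Alexa 647 lay near 0. The fixed design did not name a scan; the choice was made after technical agreement between scans and arrays had been seen and before any calls were counted in the low-gain scan. Saturated spots, at 65535, made up 1.79% to 6.73% of the spots per array in the high-gain scan. Background was corrected with normexp and an offset of 50, ratios were normalized by loess within each array, signs were turned to knockout over reference, and the 4 spots of a probe position and then the 2 arrays of a culture were averaged on the log2 scale. Positions without a symbol, any control spots among them included, stayed in. Analyses used R 4.3.3 and limma 3.58.1, and plots matplotlib 3.10.9.

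Oxygen (low minus high) and light (light minus dark) were fitted together in limma (lmFit and eBayes) on the 4 culture means, which left 1 residual degree of freedom, with 1.83 prior degrees of freedom added. Each SE given for these effects is limma's moderated SE, drawn from the gene's residual and from a prior variance shared by all positions. Where the residual was small the SE stayed near 0.08. That value reflects the prior and not the measured spread of the gene. P-values were adjusted by Benjamini-Hochberg over 2688 positions, with a threshold of 0.05. The residual is the light-by-oxygen difference, which therefore has no test. For the ratios to the reference none was planned; they were tested in limma after the values were seen, over the 4 culture means and over 8 arrays with a dye term. Gene lists with at least 4 measured members were tested with limma's camera at a preset correlation of 0.01 and with an estimated correlation, and list medians were ranked among 10000 random lists matched on signal. Of the 26 lists fixed beforehand, 17 had at least 1 measured member, 8 had at least 4 and 9 had none: carotenoid and retinal synthesis, flagella, gas vesicles, DMSO and TMAO respiration, ATP synthase, RNA polymerase, general transcription factors, iron and metal transport, and insertion sequences. A further 9 lists were chosen from the symbols on the arrays before the values of their genes were seen.

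Named genes followed a rule set before the data were examined: for each effect, up to 12 higher and 12 lower with the largest change passing the test, filled with the largest changes of the same sign in both culture pairs and both dye orientations and with signal above the lower quartile; all measured genes of the knocked-out, bacteriorhodopsin, retinal protein, arginine fermentation and DMSO lists; and up to 4 genes per other described list, of which the 2 largest were taken. For the light-by-oxygen difference it took the 10 largest of the same sign in both orientations, and for the reference up to 6 in each direction at least 2-fold away on all 8 arrays. Positions without a symbol are given as counts. Named genes not above local background on both arrays of a culture (10) or saturated on both (4) were passed over when examples were chosen.

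The steps were tested on simulated data. With 200 genes changed in the arrays' own intensities out of 2688 tested, the oxygen comparison called 15 of 67 genes changed 2-fold, 45 of 67 changed 4-fold and 45 of 66 changed 8-fold, and 0 unchanged genes. The light comparison called 0 of 67, 34 of 67 and 35 of 66. The changed genes were drawn only from positions above local background on all 8 arrays. No spot of theirs reached a mean intensity of 65535 in the knockout channel. Changed intensities were not capped at that value. These rates therefore do not cover dim positions or the limit that saturation sets. A 2-fold change, 1 on the log2 scale, was recovered at a median of 0.78 for oxygen and 0.76 for light, so ratios are compressed. In 20 simulations of 2688 unchanged genes for oxygen, 2 made a call. Their 4 culture values per gene were drawn from the variance of the fit itself, so array, dye and normalization steps were not tested there.

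Alternatives fixed before the data were examined were no background correction, plain subtraction, median centring, scaling between arrays, leaving out dim probes, fits over 8 arrays, a single factor, a variance trend with robust prior, each dye orientation alone, leaving out the 2 arrays numbered apart from the rest, the deposited value table, the median over spots, leaving out each array, and a 2-fold threshold. The low-gain scan without background correction, a dye term, the series of array numbers as a block and adjustment over named genes alone were chosen after seeing the data.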

Results

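Transcript levels were measured in the archaeon Halobacterium salinarum NRC-1, in a strain that per the labels lacks ura3 and htr1. The htr1 gene encodes the transducer that passes signals from sensory rhodopsin I to the chemotaxis system. Cultures of 50 mL in 125 mL flasks of rich medium were harvested in mid-logarithmic growth. They were shaken at 210 rpm (high oxygen) or at 100 rpm (low oxygen), in the light or in the dark. Each of the 4 conditions was represented by 1 RNA sample, taken here as 1 culture, which was hybridised on 2 arrays with the dyes exchanged against a common reference RNA of NRC-1. The data set thus held 8 two-colour arrays of 10752 spots, or 2688 probe positions of 4 spots each, of which 133 carried a gene symbol and 2555 had none in the annotation used. The number of cultures limits the precision: every factor level had 2 cultures and every condition 1. On the arrays, the median intensity in the knockout channel ranged from 3341 to 12948 over a median local background of 1876 to 5186. Between 78.8% and 99.1% of the probe positions exceeded the local background in that channel. Of the named genes, 118 did so on all 8 arrays. The second high-oxygen dark array stood apart, with a median intensity of 12948 against at most 6475 on the others, an SD of log2 ratios of 0.75 against 0.25 to 0.36, and a correlation between the 2 sides of the slide of 0.736 against at most 0.389.

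The knocked-out genes were examined first, as a check of the labels. The log2 ratio of knockout culture to reference was -0.46 ± 0.06 (SD, n = 4 cultures) for htr1 and -0.54 ± 0.18 (SD, n = 4 cultures) for pyrF, the orotidine-phosphate decarboxylase gene also called ura3. Both genes lay below the reference on all 8 arrays, with htr1 between -0.63 and -0.23 and pyrF between -1.06 and -0.24. The neighbouring sop1, which encodes sensory rhodopsin I, had a log2 ratio of -0.08 ± 0.06 (SD, n = 4 cultures) and lay below the reference on 4 of the 8 arrays. The size depended on the processing: htr1 was at -0.30 without background correction, -0.63 with plain subtraction and -0.28 in the authors' deposited values, and pyrF at -0.29, -0.73 and -0.20, with -0.20 in the low-gain scan. In the knockout channel the htr1 probe was above local background on 8 of 8 arrays (signal percentile 56.4) and the pyrF probe on 7 of 8, so the array values do not show that the genes were absent. Dyes were assigned from the labels, and a wrong assignment would turn the sign of an array's ratios. Whether the probes for htr1 and pyrF lie inside the deleted parts of the genes is not given in the sources used here.

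Across the knockout cultures and all conditions, named genes differed from the reference by small amounts, and 19 of the 133 lay on the same side of it on all 8 arrays. Lower than the reference were 14 of them, among them the ribosomal protein genes rpmC at -0.48 ± 0.07 and rpl12p at -0.37 ± 0.08 (log2, SD, n = 4 cultures). The others below it included carB of carbamoyl phosphate synthesis at -0.43 ± 0.09, the agmatinase gene speB at -0.34 ± 0.04, the lysyl-tRNA synthetase gene lysS at -0.32 ± 0.13 and cbiT of cobalamin synthesis at -0.30 ± 0.13. The gyrase genes gyrB and gyrA stood at -0.23 ± 0.10 and -0.19 ± 0.06, and sucC of the citrate cycle at -0.25 ± 0.09. Higher than the reference were 5: arcC, the carbamate kinase gene of arginine fermentation, at 0.38 ± 0.06, serB of serine synthesis at 0.21 ± 0.08, the excision repair gene uvrB at 0.14 ± 0.09, purE of purine synthesis at 0.14 ± 0.07, and the chemotaxis methyltransferase gene cheR at 0.11 ± 0.05. These genes were chosen after their values were seen.

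No test of the cultures against the reference was planned. In limma, tested after the values were seen, 0 of 2688 probe positions passed over the 4 culture means (599 at an unadjusted p under 0.05, 34 of them named). Over 8 arrays with a dye term, where the error is only that between hybridisations of the same RNA, 118 passed, 59 lower and 59 higher. Among these were 9 named genes, with an adjusted p of 0.0279 for htr1, rpmC and arcC and 0.0353 for pyrF. The reference was the same RNA on every array, so signs on different arrays are not independent. With independent signs about 1.04 of 133 genes would lie on the same side on all 8 arrays. Over all probe positions 122 were higher and 118 lower on all 8 arrays. Only 1 position, without a symbol, was at least 2-fold lower on all 8 arrays (probe 4433, log2 ratio -1.90 ± 0.14, SD, n = 4 cultures) and 0 were at least 2-fold higher. Without background correction, in the authors' deposited value table and in the low-gain scan the count of positions at least 2-fold away was 0.

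Among the gene groups, the median of the 2 measured genes of arginine fermentation, arcA (arginine deiminase) and arcC, was 0.29 above the reference, at percentile 99.4 of random lists of matched signal. The 6 measured genes of the citrate cycle had a median of -0.12, at percentile 1.94, with 5 of 6 below the reference. The 4 genes of replication had a median of -0.14 at percentile 4.24, and the 4 genes of cobalamin synthesis a median of -0.11 at percentile 4.78. These medians kept their sign under both other scalings of the arrays. The percentiles describe these hybridisations and are not a test. Apart from the knocked-out genes, the lists given here had the most extreme percentiles of all lists ranked. The others lay between percentiles 8.59 and 93.7. With many lists ranked, some extreme percentiles arise by chance.

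**Figure D1:**
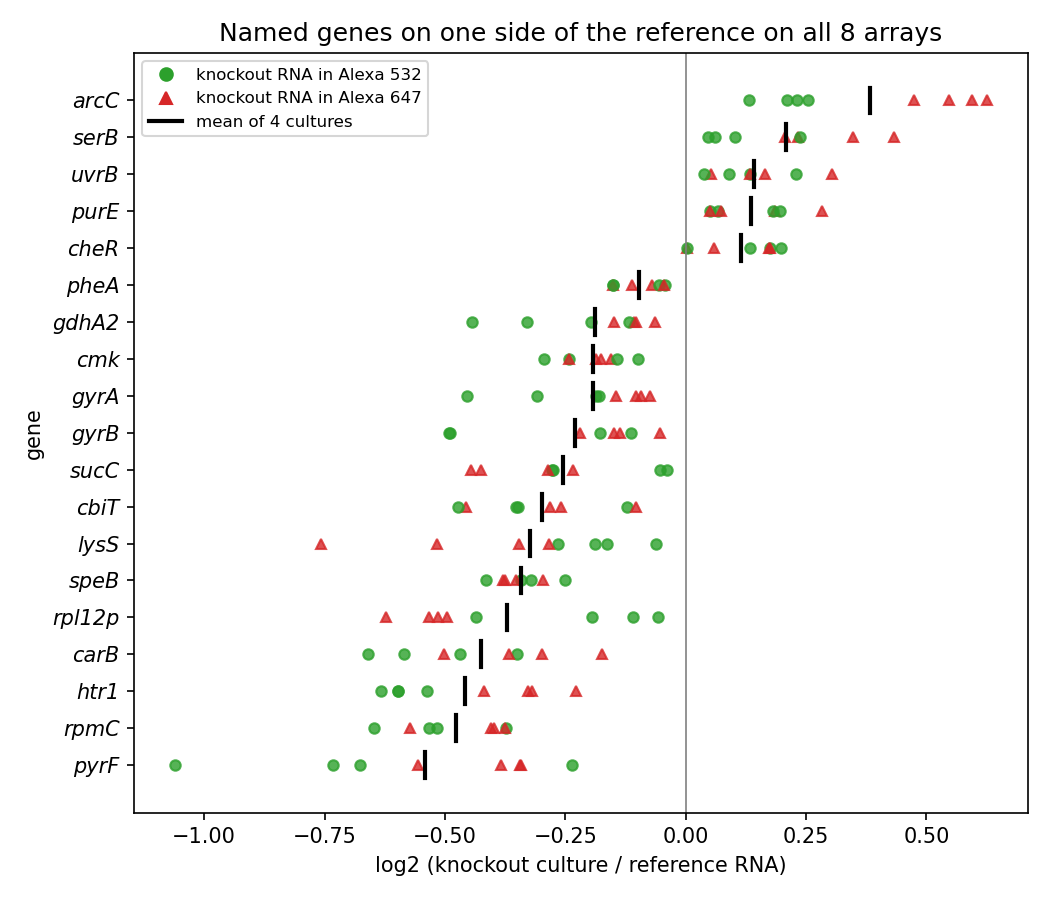
Log2 ratio of knockout culture to reference RNA (x axis) for the 19 named genes that lay on the same side of the reference on all 8 arrays. Points are single arrays, with circles for arrays carrying the knockout RNA in Alexa 532 and triangles for those carrying it in Alexa 647, and black bars are means over 4 cultures; pyrF had the lowest mean (-0.54) and arcC the highest (0.38).

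The comparison of low with high oxygen asked how the htr1 knockout responds to oxygen. No gene passed limma's test at an adjusted p of 0.05, and the smallest adjusted p was 0.746. The unadjusted p was under 0.05 for 107 of 2688 probe positions, 3.98% of them, and for 2 of the 133 named genes, glyS and the saturated gdhB. Among the named genes the differences ran from -0.38 to 0.67 (log2, low minus high oxygen), and the median 95% confidence interval reached 0.28 to either side. By the rule fixed beforehand, the largest differences of the same sign in both culture pairs and both dye orientations were 12 higher and 12 lower, none of which passed. Only mutL among these had a symbol; this mismatch repair gene stood at 0.67 ± 0.23 (SE, n = 4 cultures), with 0.31 in the light, 1.03 in the dark and an adjusted p of 0.746 in limma. It was at 0.23 without background correction, 0.19 in the authors' deposited values, 0.28 in the low-gain scan and 1.32 with plain subtraction.

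The list of other retinal proteins had 5 measured genes, of which htr1 and htr2 encode transducers. The gene hop, which encodes the chloride pump halorhodopsin, was at 0.30 ± 0.14 (log2, low minus high oxygen, SE, n = 4 cultures), with a 95% confidence interval from -0.18 to 0.77. It was at 0.09 in the light and 0.50 in the dark. The remaining 4 lay between -0.08 and -0.01, namely htr2 at -0.08 ± 0.08, sop1 at -0.06 ± 0.08, sop2 (sensory rhodopsin II) at -0.05 ± 0.08 and htr1 at -0.01 ± 0.09. The bacterio-opsin activator gene bat was at 0.11 ± 0.12, and its sign differed between the dye orientations. In arginine fermentation arcA was at 0.11 ± 0.08 and arcC at 0.02 ± 0.09. The gene pyrF, knocked out per the labels, was at 0.26 ± 0.12. None of these passed the test. An SE near 0.08 was set mostly by limma's prior variance and does not measure the spread of that gene over the cultures.

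Of the 7 transducers, 6 had lower values in low oxygen and 0 passed, with htr18 counted among the 6 though not above local background in every culture; htr8 was at -0.17 ± 0.08 (log2, SE, n = 4 cultures) and htr4 at -0.21 ± 0.19. All 4 measured chemotaxis genes had values below 0, but cheR at -0.01 ± 0.08 and cheB at -0.00064 ± 0.08 were hardly different from it. The kinase gene cheA was at -0.13 ± 0.08 and the response regulator gene cheY at -0.08 ± 0.08, and none passed. In the citrate cycle 5 of 6 were lower, with the citrate synthase gene citZ at -0.11 ± 0.08 against sucC at 0.09 ± 0.11. Of the 5 chaperone and proteasome genes 4 were lower, with the chaperone gene dnaK at -0.19 ± 0.08 against pan1, which encodes a proteasome-activating nucleotidase, at 0.19 ± 0.08. Of the 4 cobalamin genes 3 were lower, with cbiT at -0.17 ± 0.09 and cbiQ at -0.14 ± 0.09. The 4 replication genes split evenly, with orc7 at 0.35 ± 0.18 and orc8 at -0.18 ± 0.08, both for origin-binding proteins. The orc7 value was 0.09 in Alexa 532 arrays and 0.61 in Alexa 647 arrays, and 0.08 in the light and 0.62 in the dark. In arginine and nucleotide synthesis 4 of 6 were lower, with pyrB (aspartate carbamoyltransferase) at -0.26 ± 0.09; its spots were saturated in the knockout channel on 4 of 8 arrays.

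Among the 8 lists with at least 4 measured members, the smallest adjusted p of limma's camera test for oxygen was 0.615, and no gene of any list passed when adjusted over the list alone. With an estimated correlation the adjusted p was 0.970 for each of these lists. The medians of the chemotaxis, citrate cycle, chaperone, replication and nucleotide lists changed sign when arrays were centred on their median in place of loess. In limma the count of probe positions passing was 2 with the culture as a random block over 8 arrays, 1 with a variance trend and robust prior, 1 in the authors' deposited value table and 4 in the low-gain scan. None of these positions had a symbol. The random-block fit had no dye term and an estimated correlation of -0.639 between the arrays of a culture. A negative correlation narrows the error of differences between cultures, so its 2 calls carry little weight.

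The comparison of light with dark asked how illumination acts in cells labelled as lacking this transducer. No gene passed limma's test at an adjusted p of 0.05, and the smallest adjusted p was 0.797. The unadjusted p was under 0.05 for 144 of 2688 probe positions, 5.36% of them, and for 3 named genes, the histidine use genes hutI, hutG and hutU, which were above local background on 3 or 4 of the 8 arrays. By the same rule, only mutL (0.41 ± 0.23) among the 12 largest higher values and htr4 (-0.45 ± 0.19) among the 12 largest lower values had a symbol, and neither passed (log2, light minus dark, SE, n = 4 cultures). For mutL the difference was 0.77 in high oxygen and 0.05 in low oxygen. Its oxygen and light values both rest mostly on the high-oxygen dark culture, at -0.71 against the reference. Its other cultures lay between 0.06 and 0.37. The difference for htr4, which encodes a transducer, was -0.74 in high oxygen and -0.16 in low oxygen, with an adjusted p of 0.797 in limma; its probe was above local background on 7 of 8 arrays. Without background correction htr4 was at -0.16 and mutL at 0.14, and in the authors' deposited values they were at -0.21 and 0.085; with plain subtraction they were at -1.04 and 0.60.

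The list of other retinal proteins also holds the transducer genes htr1 and htr2. All 5 measured genes of the list had values at or slightly above 0 in the light, and 0 passed. Here hop was at 0.16 ± 0.14, sop1 at 0.09 ± 0.08, htr1 at 0.07 ± 0.09, sop2 at 0.04 ± 0.08 and htr2 at 0.0041 ± 0.08 (log2, SE, n = 4 cultures). The adjusted p of this list in camera was 0.431. The bacterio-opsin activator gene bat was at -0.08 ± 0.12, arcA at 0.05 ± 0.08, arcC at -0.08 ± 0.09 and pyrF at 0.09 ± 0.12. All 4 chemotaxis genes had values below 0 in the light, with cheY at -0.19 ± 0.08, cheA at -0.10 ± 0.08, cheR at -0.07 ± 0.08 and cheB at -0.03 ± 0.08. The adjusted p of this list in camera was also 0.431. In the authors' deposited values cheY and cheA were above 0, at 0.064 and 0.095.

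Of the 7 transducers 5 were higher in the light and 2 lower, htr4 and the dim htr18. In the citrate cycle 3 of 6 were higher, with citZ at 0.07 ± 0.08 and the succinate dehydrogenase gene sdhC at -0.16 ± 0.08 (log2, SE, n = 4 cultures). Of the chaperone and proteasome genes 4 of 5 were lower, with pan1 at -0.19 ± 0.08 and the proteasome subunit gene psmA at -0.11 ± 0.09. Of the cobalamin genes 3 of 4 were lower, with cbiT at -0.12 ± 0.09 and the cobaltochelatase gene cobN at -0.10 ± 0.10. Of the replication genes 3 of 4 were higher, with orc7 at 0.30 ± 0.18 and gyrB at 0.17 ± 0.08. For orc7 the oxygen and light values both rest mostly on the high-oxygen dark culture, at -0.54 against the reference. The other cultures lay between 0.03 and 0.11 for this gene. In arginine and nucleotide synthesis 4 of 6 were higher, with carB at 0.15 ± 0.08 against pyrB at -0.20 ± 0.09. The partly saturated pyrB was at 0.20 in the authors' deposited values. None of these genes passed. The medians of the chaperone and cobalamin lists changed sign with median centring, and that of the transducers with scaling between arrays.

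Among the 8 lists the smallest adjusted p of limma's camera test for light was 0.431, and it was 0.924 with an estimated correlation. Adjusted over the list alone, 0 genes of the lists fixed beforehand passed; in an added list the 3 hut genes did, with p-values that rest on signal below local background. In the values deposited by the authors, 3 lists were higher in the light at an adjusted p of 0.0377 in camera (citrate cycle, cobalamin synthesis, arginine and nucleotide synthesis), which became an adjusted p of 0.829 with an estimated correlation.

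**Figure D2:**
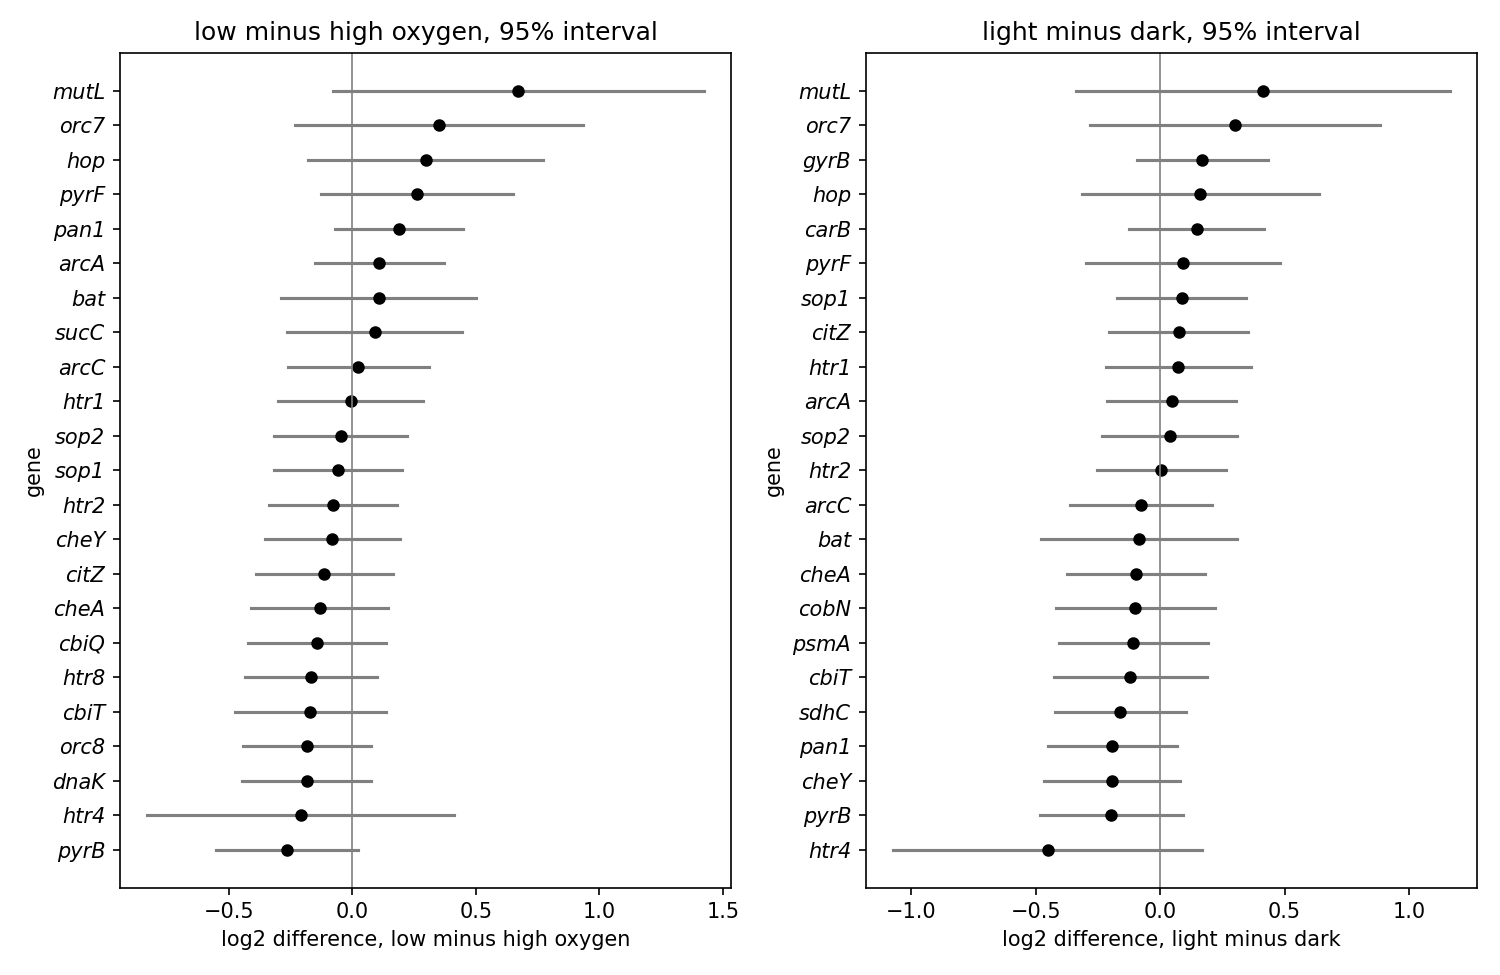
Log2 difference between low and high oxygen (left panel) and between light and dark (right panel) for the 23 genes named in each comparison. Points are limma estimates over 4 cultures and lines are 95% confidence intervals; every interval includes 0, with mutL the highest at 0.67 and 0.41.

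The light-by-oxygen difference, that is the light effect in low oxygen minus that in high oxygen, had 1 culture per condition and no test. The molybdopterin synthesis gene moaA stood at -0.89 on the log2 scale, from a light effect of 0.56 in high oxygen and -0.33 in low oxygen. The difference was -0.23 without background correction, -0.22 in the authors' deposited values and -0.073 in the low-gain scan, and leaving out 1 array gave -1.24 to -0.55. It was the only gene with a symbol among the 10 largest values of the same sign in both dye orientations. No named gene reached a 2-fold difference. Over all probe positions 132 did so, of which 100 had the same sign in both dye orientations, while 43.5% of all positions had the same sign in both. The 132 were chosen for a large mean of the 2 orientations, which by itself favours a shared sign. Their count is therefore no sign of repetition between the orientations. Over all positions the difference correlated at -0.139 between them. With dim probe positions left out, 6 remained at least 2-fold. Leaving out the second high-oxygen dark array gave 65 positions, and leaving out the first gave 329.

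Whether the oxygen and light differences exceeded the spread of the measurement was examined over all probe positions. The SD over positions was 0.23 for the oxygen difference, 0.23 for the light difference and 0.22 for the light-by-oxygen difference at the same scale (log2). Over the named genes it was 0.15, 0.16 and 0.12, with the dim hutI, hutG and hutU included. Between the 2 dye orientations, the correlation across positions was -0.0721 for oxygen, -0.111 for light and -0.139 for the light-by-oxygen difference. Across the named genes it was 0.106, 0.119 and -0.0732. Positions are not independent replicates. The 2 arrays of a single RNA correlated at -0.180 to 0.0504 over positions, whereas arrays of different cultures in the same dye orientation correlated at 0.0954 to 0.536 and means of the 2 dye-swapped arrays of different cultures at 0.240 to 0.521. These correlations do not establish that the dye labels of all arrays are right, on which the sign of every ratio rests.

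**Figure D3:**
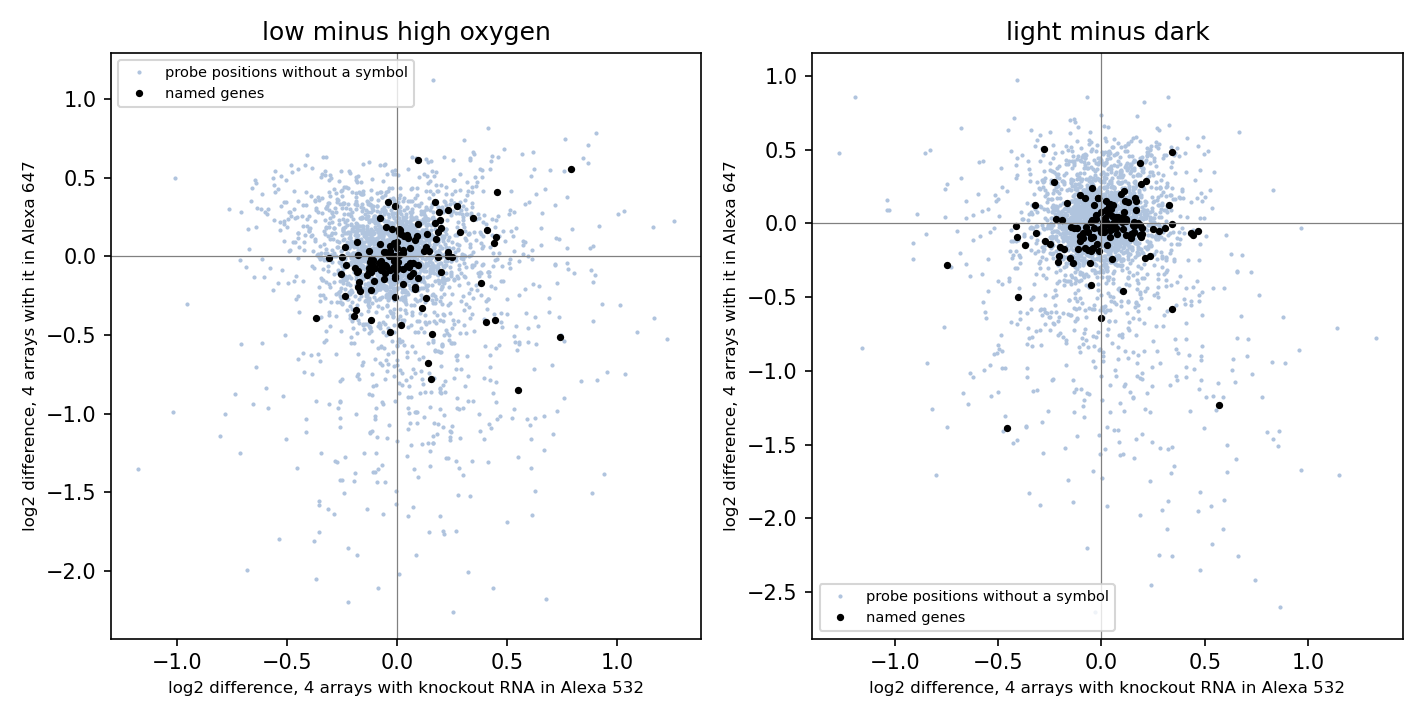
Log2 differences between low and high oxygen (left panel) and between light and dark (right panel) from the 4 arrays with the knockout RNA in Alexa 532 (x axis) against the 4 arrays with it in Alexa 647 (y axis). Each point is 1 of 2688 probe positions, with named genes in black; the correlations are -0.0721 for oxygen and -0.111 for light.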

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

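The genes named in the comparisons were searched for light effects of opposite sign in low and high oxygen, seen in both dye orientations; the difference was not tested, since each condition had 1 culture. Of 29 genes looked at, 2 met this; no chance count applies, since moaA was chosen for this difference and mutL and htr4 for the same sign in both oxygen levels. For moaA of molybdopterin synthesis the light effect was 0.56 in high oxygen and -0.33 in low oxygen, a difference of -0.89 on the log2 scale. This difference was -0.23 without background correction, -0.22 in the authors' deposited values and -0.073 in the low-gain scan. For cbiQ of cobalamin synthesis the light effect was -0.09 in high oxygen and 0.02 in low oxygen, a difference of 0.11. Over all 2688 probe positions 10.2% had such opposite signs.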

How the results depend on the processing

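Dim genes are limited by local background, and every test by 4 cultures. The low-gain scan, the dye term, the array series as a block and adjustment over named genes were chosen after seeing the data. Leaving out an array, or the 2 arrays numbered apart, leaves the culture of each such array in a single dye orientation. A dye difference then enters the contrasts, so these changes are not a measure of the array alone. Other causes of the changes below were not tested. No paired analysis was possible because the replicate labels name only the dye-swapped arrays of a culture. Camera takes no random block and no robust prior, so these were not run for gene lists.

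Light calls stayed at 0 in limma under every fit tried, with a smallest adjusted p never under 0.0583. Positions at least 2-fold for light were 10, with 0 to 146 over the alternatives and 4 to 121 on leaving out 1 array. Oxygen calls were 0 except for 2 with the culture as a random block and 1 with trend and robust prior. The authors' value table also gave 1 and the low-gain scan 4. The random block had a negative correlation of -0.639, which narrows the error behind its 2 calls. Positions at least 2-fold for oxygen were 13, with 0 to 124 over the alternatives and 2 to 116 on leaving out 1 array. Gene lists passing were 0, except 3 in the authors' values, which did not pass with an estimated correlation (adjusted p 0.829 in camera). For the light-by-oxygen difference the 132 positions became 0 without background correction, 342 with plain subtraction, 86 with scaling between arrays, 6 without dim probes, 364 with Alexa 647 arrays alone, 0 in the authors' values and 1 in the low-gain scan; leaving out 1 array gave 65 to 329. The 1 position at least 2-fold from the reference became 0 without background correction, in the authors' values and in the low-gain scan.

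None of the genes named for oxygen or light passed under any alternative. Their signs changed in 27 of 391 oxygen values and 35 of 391 light values, and in 22 and 25 of 184 when an array was left out. The 391 values include alternatives that leave every estimate as it was. These are leaving out dim probes, the fits over 8 arrays (with a dye term or the array series too), the single factor and the variance trend. No sign could change there, so the share of changed signs under the remaining alternatives is larger. Sizes changed too: of 23 genes each, 10 oxygen and 5 light values kept their sign with under 0.5 of the size in the authors' values, 9 and 10 in the low-gain scan, 5 and 7 without background correction, and 4 and 6 with median centring. Over 2 times the size were 2 oxygen and 8 light values without the 2 arrays numbered apart, 2 and 4 with plain subtraction, 3 and 2 with median centring, and 2 and 3 in the authors' values. Against the reference htr1 was at -0.59 in Alexa 532 arrays and -0.32 in Alexa 647 arrays. The values of changed sign (log2) follow.

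For oxygen, the authors' values gave pyrB 0.035, dnaK 0.00478, bat -0.069 and cheY 0.071. The low-gain scan gave dnaK 0.068, bat -0.085, sop1 0.031 and sucC -0.064. Median centring gave dnaK 0.030, bat -0.019, cbiQ 0.014, sop2 0.00777, cheY 0.12 and cheA 0.013. The median over spots gave sop2 0.016. No background correction gave bat -0.046 and sop1 0.011. Plain background subtraction gave htr4 0.13. Alexa 532 arrays alone gave htr4 0.017. Alexa 647 arrays alone gave bat -0.17. Without the 2 arrays numbered apart the values were cbiQ 0.034, sop1 0.11, htr1 0.12, sop2 0.18, htr2 0.018, cheY 0.081 and cheA 0.088. Leaving out 1 array, bat ran from -0.13 to 0.34, arcA from -0.0054 to 0.22, arcC from -0.072 to 0.12, sop1 from -0.20 to 0.085, htr1 from -0.084 to 0.072, sop2 from -0.18 to 0.083, cheY from -0.16 to 0.00158 and sucC from -0.00715 to 0.19. The signs of sop1, htr1 and sop2 changed in the same 4 removals. These were the Alexa 647 array of a high-oxygen culture or the Alexa 532 array of a low-oxygen culture. Against the reference, sop1 was at -0.40 to -0.24 on Alexa 532 arrays and 0.046 to 0.27 on Alexa 647 arrays. The sign changes of these genes therefore went with the dye left out. With the sign kept, the values on leaving out 1 array ran for oxygen over htr8 -0.22 to -0.12, cbiT -0.22 to -0.12, citZ -0.16 to -0.065, pyrB -0.36 to -0.17, hop 0.22 to 0.37, dnaK -0.22 to -0.15, cbiQ -0.25 to -0.039, mutL 0.55 to 0.79, htr4 -0.41 to -0.007, htr2 -0.14 to -0.017, cheA -0.25 to -0.018, orc7 0.19 to 0.51, orc8 -0.23 to -0.13, pan1 0.10 to 0.27 and pyrF 0.083 to 0.44.

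For light, the authors' values gave cbiT 0.072, pyrB 0.20, hop -0.078, arcC 0.14, sop1 -0.017, cheY 0.064, cheA 0.095, cobN 0.13, psmA 0.065, sdhC 0.029 and pyrF -0.082. The low-gain scan gave hop -0.018, arcA -0.019, sop1 -0.022, htr1 -0.00934 and sop2 -0.069. Median centring gave cbiT 0.036, arcC 0.059, cheA 0.014, cobN 0.034, psmA 0.15 and pyrF -0.00105. Scaling between arrays gave htr1 -0.00801, htr2 -0.00865 and pyrF -0.015. No background correction gave hop -0.00766. Plain background subtraction gave pyrF -0.064. Alexa 532 arrays alone gave arcA -0.079, sop2 -0.000805 and htr2 -0.025. Alexa 647 arrays alone gave gyrB -0.00631 and bat 0.022. Without the 2 arrays numbered apart the values were bat 0.29, arcC 0.096 and cheA 0.12. Leaving out 1 array, bat ran from -0.32 to 0.15, arcA from -0.069 to 0.16, arcC from -0.17 to 0.020, sop1 from -0.055 to 0.23, htr1 from -0.00441 to 0.15, sop2 from -0.092 to 0.17, htr2 from -0.059 to 0.067, cheA from -0.21 to 0.017 and pyrF from -0.089 to 0.27. With the sign kept, the values on leaving out 1 array ran for light over gyrB 0.060 to 0.28, cbiT -0.17 to -0.067, citZ 0.026 to 0.12, pyrB -0.29 to -0.097, hop 0.086 to 0.24, carB 0.045 to 0.25, mutL 0.29 to 0.53, htr4 -0.65 to -0.25, cheY -0.28 to -0.11, cobN -0.18 to -0.023, orc7 0.14 to 0.46, psmA -0.18 to -0.033, sdhC -0.28 to -0.042 and pan1 -0.28 to -0.11.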

Other observations

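Some gene groups not described above were chosen from the annotation before the values of their genes were seen, and glyS and the haem genes were singled out after their values were seen. Of the 6 measured genes of histidine synthesis 5 were lower in low oxygen, with hisA at -0.16 ± 0.09 and hisB at -0.13 ± 0.08 (log2, SE, n = 4 cultures), and the adjusted p of the list in limma's camera was 0.509. In glutamate metabolism gdhA2 was at 0.12 ± 0.09 and glnA at 0.09 ± 0.08; the adjusted p of that list, also 0.509, includes the saturated gdhB. For light the smallest adjusted p among these lists was 0.945. Both measured haem synthesis genes were lower in low oxygen, hemL at -0.29 ± 0.11 and hemA at -0.11 ± 0.08. The glycyl-tRNA synthetase gene glyS was at -0.38 ± 0.08 for oxygen and -0.26 ± 0.08 for light, with an adjusted p in limma of 0.746 and 0.797. It had the same sign in both culture pairs and both dye orientations of each. That is common, as 37.2% of all probe positions for oxygen and 36.3% for light had it. Leaving out 1 array, glyS ran from -0.58 to -0.19 for oxygen and from -0.46 to -0.062 for light, and for oxygen hisA ran from -0.30 to -0.025, hisB from -0.29 to 0.022, gdhA2 from 0.042 to 0.19, glnA from 0.059 to 0.12, hemL from -0.36 to -0.22 and hemA from -0.32 to 0.10. Over the other alternatives the values ran for oxygen from -0.47 to -0.037 (glyS), -0.31 to 0.053 (hisA), -0.27 to 0.058 (hisB), -0.050 to 0.23 (gdhA2), -0.038 to 0.36 (glnA), -0.38 to 0.0049 (hemL) and -0.32 to -0.060 (hemA), and for light from -0.66 to 0.086 (glyS).

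A bright probe position without a symbol (probe 3453, signal percentile 92.3) was called for oxygen in limma under 2 alternatives, at 0.62 (adjusted p 0.00329) in the authors' deposited value table and at 0.63 (adjusted p 0.00832) in the low-gain scan. In the main values it was at 0.35, with an adjusted p of 0.746 (probe_3453). Of its 32 high-gain spots 5 were saturated. It was the only one of 7 positions called under any alternative that was called in more than 1.

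Some explanations set out below were written after values bearing on them were seen: noise between hybridisations of the same RNA (over all positions and over brighter ones), the single array as the source of the hut values, and local background correction for the genes set against the reference. The spread by resampling of 1.09 was also added after that value was seen, since without it the second high-oxygen dark array would have been ruled out. The verdict on the spatial gradient was first reached by the bound set beforehand. It was withdrawn and then restored, with a spread by resampling, after its value of 0.036 was seen. It is limited below to gradients that also shift brighter spots.

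The oxygen and light differences were hardly wider over probe positions (SD 0.23 and 0.23) than the light-by-oxygen difference at the same scale (SD 0.22). Over the named genes the SDs were 0.15 and 0.16 against 0.12, but the width for light includes the dim hutI, hutG and hutU. The hardly greater width over probe positions was looked at further. Noise between hybridisations may account for this, since the oxygen difference correlated at -0.0721 between the 2 dye orientations. Over probe positions above the lower quartile of signal the correlation was 0.165 for oxygen and 0.0326 for light, which leaves this open for brighter probes in the oxygen difference. At the same positions it was -0.217 for the light-by-oxygen difference, and the source of that negative value was not tested. The second high-oxygen dark array, whose log2 ratios had an SD of 0.75 against 0.25 to 0.36 on the others, stays open as a source too. Its ratios repeated between the 2 sides of the slide, with a correlation of 0.736, so its width is not only noise of single spots. Without it the oxygen difference was 1.09 times as wide as the light-by-oxygen difference, with an SD of 0.0249 over 200 resamples. That was under the bound set beforehand for ruling the array out, but by less than that spread. Leaving it out also leaves the high-oxygen dark culture in 1 dye orientation, so a dye difference enters both contrasts alike. A true response below the size these arrays resolve remains open and untested.

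The genes of histidine use, hutI, hutG and hutU, had lower values in the light, but they were above local background on neither array of the high-oxygen light culture, so no fold is given. The 67 neighbouring probe positions had a median light effect of 0.036, with an SD of 0.014 over 200 resamples. That met the bound set beforehand and argues against a spatial gradient that also shifts brighter spots. Of these neighbours 59 were above local background on all 8 arrays, unlike the hut genes, and they were not matched on signal. A gradient that shifts mainly dim spots therefore stays open. Noise of dim spots stays open, as 4.37% of 10000 random triples of similar signal had a mean as large, and so does a single array, without which the genes' median was -0.39 with signal below background taken as measured. An effect of light on these genes also stays open and untested.

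Of the 19 named genes on the same side of the reference on all 8 arrays, 100% kept their sign and at least 0.5 of their size with median centring. Without background correction 94.7% did so. These are means over dye-swapped arrays, where a dye difference that varies with intensity largely cancels with or without these steps. The genes were also chosen for the same sign in both dye orientations, so much of this outcome was set beforehand. The check argues only against an effect of loess or background correction that does not turn with the dye. In the deposited value table all 19 kept their sign but only 15 at least 0.5 of their size, and in the low-gain scan 19 and 16; in the former cheR was at 0.0077 and pyrF at -0.20. The dye labels were not verified. As a hypothesis, the ratios may reflect a difference between the knockout cultures and the reference RNA, which differ in strain and culture together; the design holds no parent strain grown alongside, and which of these accounts for it was not tested.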
